A study of Tachysurus vachellii with 6 samples.

How the data were processed

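Small RNA of extracellular vesicles isolated from the liver of the darkbarbel catfish, Pelteobagrus vachellii (Tachysurus vachellii), was profiled in 6 libraries. Per the labels' protocols, fish were held in water at a dissolved oxygen of 6.8 mg/L or in sealed water bubbled with nitrogen to about 1 mg/L, and vesicles were prepared from liver tissue. The sample titles name the tissue and not the vesicles. The comparison was 3 libraries of hypoxia at 4 h against 3 libraries of normoxia at 4 h. The labels do not say that each library came from a separate fish or pool of fish, so that p-values measure only the spread between these samples, which may be technical.

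Per the labels' protocols, RNA was ligated to adapters at both ends, reverse transcribed, amplified by PCR, selected on a gel, and sequenced on a NovaSeq X Plus instrument, with reads truncated to single ends. The aligner, the miRNA caller, the genome build, the filters and the rules of annotation are not given in the sources used here. No molecular identifiers are mentioned, so intervals and floors derived from counts cover counting error only.

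The authors deposited 1 table of estimated counts, with a name, a sequence and an unscaled value per library in each of 1088 rows. It held 874 distinct sequences under 942 names, and 195 sequences were listed more than once, always with the same value in a library. Values were not all whole: of the nonzero values, 70.0% lay within 1e-06 of a whole number. Among sequences listed 2 times, 50.2% of nonzero values were whole as listed and 95.0% after multiplication by 2. Sequences listed 1 time were whole in 86.5% of nonzero values and in 97.4% after doubling, and the few sequences listed 3 and 7 times reached 66.7% and 0% after multiplication by their listings. Division among listings therefore accounts for part of the fractions only. Listings of 1 sequence were summed on this basis. In 18 cases, rows of the same precursor held different sequences with identical values in all 6 libraries, and these were joined and the value was taken once per listing of a sequence. This gave 841 entries, of which 535 carried names of known miRNAs and 306 carried names starting with PC, read here as predicted miRNAs. After summing, 89.0% of nonzero values were whole. The rule of summing was set after a first fit of 521 sequences kept apart had been seen. That handling is among the alternatives. Names are printed as deposited. The prefix gives the species of the matched miRNA, and the meaning of the suffixes is not given in the sources used here. The design fixed before the data were examined had assumed whole counts and 1 row per name.

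Estimated counts were rounded to whole numbers. Totals per library ranged from 2038301 to 8497217 counts. Entries were filtered with filterByExpr, scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test, glmQLFit and glmQLFTest) on the 2 groups without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. All adjusted p-values of entries come from this test unless another is named. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of F. Abundance is given as CPM, the count as a share of the TMM-scaled library total, as mean ± SD over 3 libraries. On the unscaled library totals, a count of 3 corresponded to 0.353 to 1.47 CPM across libraries.

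Lists of miRNAs were fixed before the data were examined and matched by family number, with predicted entries left out. They covered hypoxia-associated, hepatocyte, lipid and glucose metabolism, erythrocyte, leukocyte, endothelial, skeletal and cardiac muscle, mesenchymal and smooth muscle, biliary and other epithelium, neural, pancreas, miR-17-92 and paralog clusters, sensory cluster, let-7, miR-10 with miR-99, miR-100 and miR-125, miR-30, miR-15/16, p53-linked and fish maternal-clearance miRNAs. Lists with at least 3 tested entries, 16 in all, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. An estimated correlation and the directional fry test were alternatives. Library composition was compared with exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1.

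The entries named in the text were set by a rule written before the data were examined. It took called entries with a mean of at least 10 CPM, up to 12 per direction by absolute log2 fold change, the 5 most abundant entries of each group, every miR-210 and miR-122 entry, and up to 4 members of each list, called ones first and then by abundance. Entries that the filter left untested are not named. Entries outside the rule are said to have been chosen after their values were seen.

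The fits were tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, for hypoxia against normoxia. With 504 entries tested, log2 changes of 0.5, 1 and 2 were simulated in 63, 66 and 65 of them. edgeR recovered 30.2% of changes of 0.5, 71.2% of changes of 1 and 96.9% of changes of 2. Of its calls 2.3% were false. So many changed entries ease the Benjamini-Hochberg adjustment, so recovery may be lower where fewer entries change. No trend on GC content or length was simulated. With nothing changed edgeR called 1 of 500 entries. Camera called the 1 raised list of 10 simulated lists and no other. Entries were simulated independently and list members drawn at random, so this does not show how camera behaves on lists of correlated members.

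The alternatives set before the data were examined were the size factors of DESeq2 in edgeR, total counts only, upper-quartile scaling, no filter, a filter of at least 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, summing by family and arm, known miRNAs only, and an added 2-fold threshold. Chosen after seeing the data were each entry taken at its listed value without summing, every sequence kept apart, and offsets from a linear trend per library on GC content and length, fitted on 329 entries. R 4.3.3, Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and matplotlib 3.10.9 were used. The reference supplied was a table of gene names without miRNA genes, and no genome sequence was used here, so no coordinates are given.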

Results

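Vesicles released within the liver carry small RNAs, and the comparison asked which miRNAs differed in liver-derived vesicles of the darkbarbel catfish after 4 h of hypoxia at a dissolved oxygen of 1 mg/L, against normoxia at 6.8 mg/L. Each group had 3 libraries. The hypoxia libraries held 2038301, 7234216 and 6039290 counts in replicates 1, 2 and 3, and the normoxia libraries held 8497217, 6003250 and 5572737. Hypoxia replicate 1 was the shallowest and stood apart from the others. It had 462 entries detected, against 681 and 657 in hypoxia replicates 2 and 3 and 643 to 725 in normoxia. With all libraries thinned to its total it had 462 against 628 to 692 in the other 5, so thinning did not close the gap. Filters applied before deposit are not known, so this cannot exclude depth as the cause. Across entries the log2 CPM of hypoxia replicate 1 correlated with those of the others at Pearson r of 0.948 to 0.970. Pairs among the other 5 reached 0.976 or more. Entries are not independent replicates. No pair of replicates agreed within sampling noise, with chi-square per degree of freedom of 43.7 or more, and all were kept as separate samples.

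Both arms of miR-210, the best known hypoxia-induced miRNA, rose in hypoxia by 2.53-fold and 2.37-fold, and the erythrocyte miRNAs miR-451 and miR-144-3p rose with them. miR-20a-5p, miR-26a-5p and a miR-146b-3p entry fell. Of 519 entries tested, which held 99.98% of all counts, 14 passed the threshold, 8 higher and 6 lower in hypoxia. In all 14 the 3 hypoxia libraries lay to one side of the 3 normoxia libraries. This held for 135 tested entries (26%), where chance gives 10% for a single entry. An unadjusted edgeR p under 0.05 was reached by 96 entries, where 26 were expected by chance. Entries shared trends of their libraries, so neither excess was tested against chance. The threshold was close for most of the 14, because 10 of them shared an edgeR Benjamini-Hochberg adjusted p of 0.0494. The count was 5 with total counts only (5 higher, 0 lower), 13 with upper-quartile scaling (10 higher, 3 lower), 51 with DESeq2 (27 higher, 24 lower), 22 with limma-voom and 3 (all higher) with offsets for GC content and length. It was 1 without hypoxia replicate 1, 52 without hypoxia replicate 2, 2 without hypoxia replicate 3, 1 without normoxia replicate 1, 0 without normoxia replicate 2 and 5 without normoxia replicate 3.

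**Figure D1:**
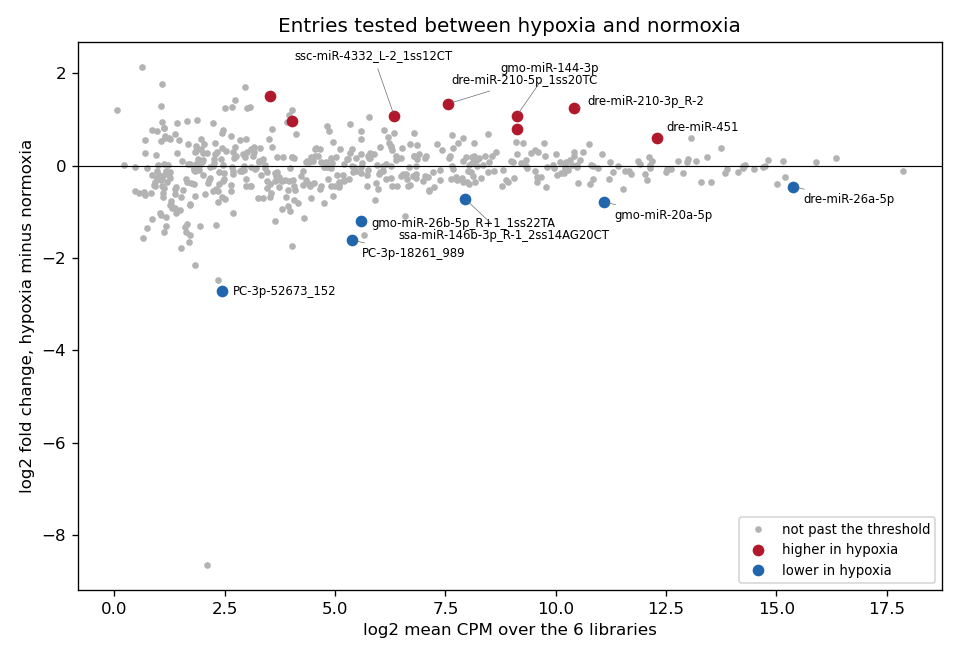
Each point is 1 of 519 tested entries, with the log2 of its mean CPM over 6 libraries on the x axis and the log2 fold change, hypoxia minus normoxia, on the y axis. Red points are the 8 entries that rose and blue points the 6 that fell, and the lowest grey point is a predicted entry without counts in any hypoxia library, whose fitted value is no bound.

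The 5p arm of miR-210 (dre-miR-210-5p_1ss20TC, AGCCACTGACTAACGCACACTG) measured 272 ± 18.97 CPM in hypoxia and 107.2 ± 9.96 CPM in normoxia (SD, n = 3 each). Its log2 fold change was 1.34 ± 0.14 (SE), with an edgeR Benjamini-Hochberg adjusted p of 0.0021. The more abundant 3p arm (dre-miR-210-3p_R-2, CTGTGCGTGTGACAGCGGCT) measured 1917 ± 438 CPM in hypoxia and 808 ± 37.7 CPM in normoxia, a log2 fold change of 1.25 ± 0.17 (edgeR, Benjamini-Hochberg adjusted p = 0.0080). In hypoxia replicates 1, 2 and 3 the 3p arm stood at 2207, 1413 and 2132 CPM, against 765 to 835 CPM in normoxia. With offsets for GC content and length both arms passed, at log2 fold changes of 1.32 and 0.97. Without normoxia replicate 2 neither passed, at log2 fold changes of 1.27 and 1.18 (edgeR, Benjamini-Hochberg adjusted p = 0.056 and 0.162), and the 3p arm also missed the threshold without hypoxia replicate 1, hypoxia replicate 3 or normoxia replicate 1, at 1.19, 1.18 and 1.32 (edgeR, Benjamini-Hochberg adjusted p = 0.053, 0.067 and 0.061).

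**Figure D2:**
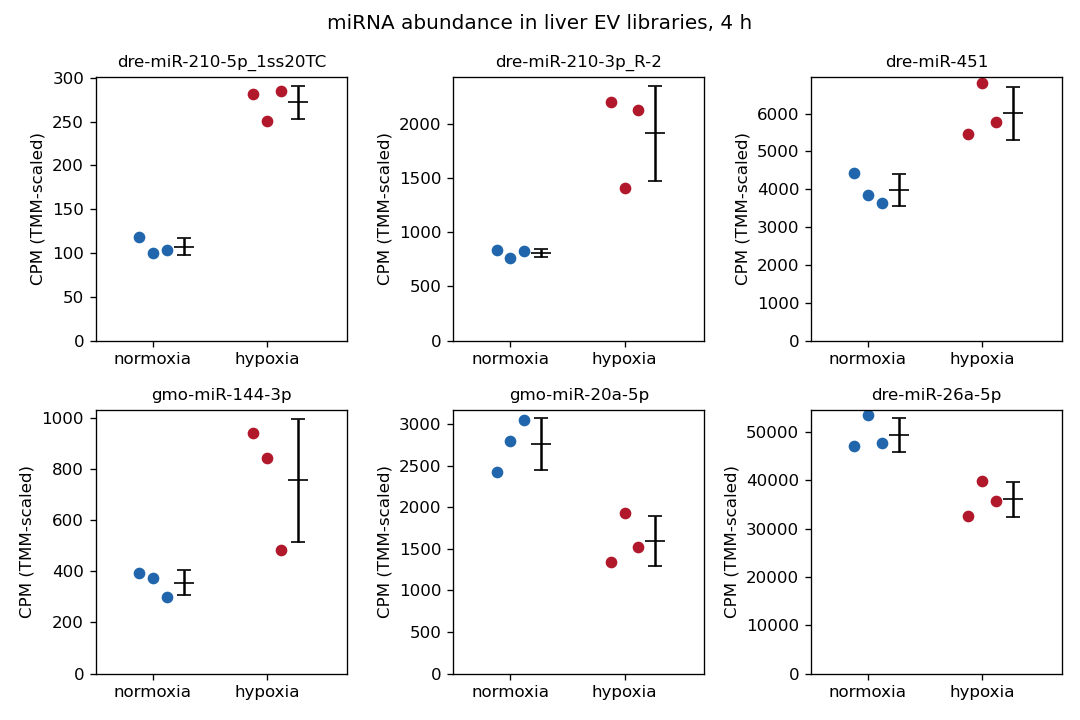
Dots give the CPM, scaled by TMM factors, of 6 called entries in each of 3 normoxia (blue) and 3 hypoxia (red) libraries, and the bar beside them gives mean ± SD. The 2 arms of miR-210, miR-451 and miR-144-3p lay higher in every hypoxia library, and miR-20a-5p and miR-26a-5p lay lower.

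Among the 54 tested entries of hypoxia-associated families, 2 rose (the miR-210 arms), 2 fell and 50 did not pass. Those that fell were dre-miR-26a-5p and a rarer miR-26 entry, gmo-miR-26b-5p_R+1_1ss22TA. Adjusted over the list alone, 3 rose and 4 fell. The list did not pass (camera direction up, median log2 difference -0.09, Benjamini-Hochberg adjusted p = 0.992), and the direction of the test and the sign of the median differed. Without hypoxia replicate 1 the median was 0.06.

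The erythrocyte list held 7 tested entries, of which 2 rose and 5 did not pass. dre-miR-451, a miRNA abundant in red blood cells, measured 6011 ± 702 CPM in hypoxia and 3971 ± 420 CPM in normoxia, a log2 fold change of 0.60 ± 0.13 (edgeR, Benjamini-Hochberg adjusted p = 0.0494). gmo-miR-144-3p, made from the same cluster, measured 755 ± 239 CPM and 355 ± 48.7 CPM, a log2 fold change of 1.09 ± 0.23 at the same adjusted p (edgeR, Benjamini-Hochberg adjusted p = 0.0494). The opposite strand of miR-451, dre-mir-451-p3, had a log2 fold change of 0.02 ± 0.17, and a miR-144a entry, oni-miR-144a_L-1R+1_1ss11TA, one of 0.35 ± 0.20. Adjusted over the list alone, 2 rose and 1 fell, the latter being bta-miR-486, at 10.4 CPM in hypoxia and 21.2 CPM in normoxia, which is named after its values were seen. As a whole the list did not pass (camera, median log2 difference 0.31, Benjamini-Hochberg adjusted p = 0.295). Its median was 0.10 without hypoxia replicate 2 and 0.52 without hypoxia replicate 3. With offsets for GC content and length miR-451 passed at a log2 fold change of 0.76, while miR-144-3p, at 1.22 ± 0.26, did not (edgeR, Benjamini-Hochberg adjusted p = 0.071). With total counts only miR-144-3p did not pass either, at 1.13 (edgeR, Benjamini-Hochberg adjusted p = 0.056). With 1 library left out at a time, miR-451 passed only without hypoxia replicate 2 (log2 fold change 0.51) and miR-144-3p only without hypoxia replicate 2 (1.01) or 3 (1.34).

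Of the entries that fell, dre-miR-26a-5p was the most abundant, at 36102 ± 3603 CPM in hypoxia and 49436 ± 3520 CPM in normoxia, a log2 fold change of -0.45 ± 0.10. gmo-miR-26b-5p_R+1_1ss22TA measured 28.7 ± 10.98 CPM and 67.4 ± 8.34 CPM, a log2 fold change of -1.19 ± 0.26. These miR-26 sequences are close to one another and the rule by which reads were divided is not known, so their separate values are uncertain. gmo-miR-20a-5p, a member of the miR-17-92 family of clusters that promote cell proliferation, measured 1600 ± 301 CPM and 2761 ± 318 CPM, a log2 fold change of -0.79 ± 0.15. ssa-miR-146b-3p_R-1_2ss14AG20CT, of a family that restrains inflammatory signalling, measured 186 ± 27.4 CPM and 307 ± 33.6 CPM, a log2 fold change of -0.72 ± 0.16. With offsets for GC content and length none of these 4 passed. Their log2 fold changes were then -0.33 ± 0.09, -0.96 ± 0.22, -0.59 ± 0.14 and -0.59 ± 0.13 in the order given (edgeR, Benjamini-Hochberg adjusted p from 0.071 to 0.110). With 1 library left out at a time, these 4 passed only without hypoxia replicate 2. None of the 4 passed with total counts only (edgeR, Benjamini-Hochberg adjusted p = 0.056). With upper-quartile scaling both miR-26 entries and the miR-146b-3p entry did not pass. Both miR-26 calls also rested on the summing of listings, a rule set after a first fit had been seen, since at listed values they did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.060).

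The other calls were entries of less certain identity. ssc-miR-4332_L-2_1ss12CT, of 18 nt and 94.4% GC, measured 110 ± 17.3 CPM in hypoxia and 51.9 ± 6.46 CPM in normoxia (log2 fold change 1.08 ± 0.18), and mmu-mir-6236-p5_2, also of 18 nt, measured 706 ± 158 CPM and 407 ± 13.5 CPM (0.79 ± 0.17). Both carry the names of mammalian miRNAs. With offsets for GC content and length they measured 0.38 ± 0.17 and 0.44 ± 0.18 on the log2 scale and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.272 and 0.241). The remaining 4 were predicted. PC-3p-36048_315 (TCTGGAATGGAAGCCTGCACT) rose from 5.98 ± 1.51 CPM to 17.0 ± 2.85 CPM and PC-5p-45719_199 (CAGGACTTAGCCACATGTGAAC) from 11.1 ± 1.15 CPM to 21.5 ± 2.66 CPM. PC-3p-18261_989 (ACGGGTGTCTTGTCCGATGATC) fell from 63.7 ± 21.5 CPM to 20.2 ± 9.88 CPM. PC-3p-52673_152 shares the first 21 of its 22 bases and fell too, with a log2 fold change of -2.72. It lies below the 10 CPM floor for named entries and is named after its values were seen. With 1 library left out at a time, these 6 entries passed without hypoxia replicate 2, and ssc-miR-4332_L-2_1ss12CT also without normoxia replicate 3. With total counts only mmu-mir-6236-p5_2, PC-5p-45719_199, PC-3p-18261_989 and PC-3p-52673_152 did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.056), and with annotated entries only mmu-mir-6236-p5_2 did not (0.063 by the same test). With offsets for GC content and length the 4 predicted entries did not pass, at log2 fold changes of 1.43 ± 0.26, 0.99 ± 0.19, -1.61 ± 0.36 and -2.68 ± 0.58 in the order they were introduced (edgeR, Benjamini-Hochberg adjusted p from 0.054 to 0.071), and with limma-voom PC-3p-52673_152 did not (adjusted p = 0.089).

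The most abundant miRNAs of the vesicles did not pass, except miR-26a-5p. miR-122, the main hepatocyte miRNA (tni-miR-122_R-1), took 228943 ± 20041 CPM in hypoxia and 246967 ± 6027 CPM in normoxia, a log2 fold change of -0.11 ± 0.08 (edgeR, Benjamini-Hochberg adjusted p = 0.519). The other tested miR-122 entries, dre-miR-122_L+1R-1, pol-miR-122-3p_R-1_1ss19TA and abu-miR-122_R+2, had log2 fold changes of 0.08, -0.17 and -0.44 and did not pass. oni-let-7e, dre-miR-22a-3p, dre-miR-199-5p and dre-miR-148_R-1 had log2 fold changes of 0.16, 0.08, 0.10 and -0.25. None of the 21 tested hepatocyte entries passed, 17 of them with a fold change below 1 (camera, Benjamini-Hochberg adjusted p = 0.295). Of 23 entries of families linked to lipid and glucose metabolism, 0 passed, where 5 had an unadjusted p under 0.05. The list's camera direction was up and its median log2 difference -0.09 (Benjamini-Hochberg adjusted p = 0.992), and medians with 1 library left out lay at -0.12 to 0.00. Its member oni-miR-143_1ss20TA lay at 0.02 ± 0.18.

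No list passed camera, and 3 had an unadjusted camera p under 0.05. The lowest camera p belonged to the miR-17-92 and paralog clusters, in which 1 of 27 tested entries fell (miR-20a-5p), 0 rose and 23 had a lower fold (median log2 difference -0.28, Benjamini-Hochberg adjusted p = 0.084, adjusted p = 0.521 with an estimated correlation). Without hypoxia replicate 1 its median was -0.12. Its most abundant member, dre-miR-92a-3p, had a log2 fold change of 0.19 ± 0.16. In the miR-15/16 family 10 of 12 entries had a higher fold and 0 passed, among them ipu-miR-16b at 0.29 ± 0.11 and dre-miR-16c-5p at 0.27 ± 0.12 (median 0.28, camera, Benjamini-Hochberg adjusted p = 0.087, adjusted p = 0.521 with an estimated correlation). Adjusted over the list alone, 1 rose, ccr-miR-457a_L+1R+1, which is named after its values were seen. Fry, which does not compare a list with other entries, passed these 2 lists and skeletal and cardiac muscle, each at a Benjamini-Hochberg adjusted p of 0.0458. Without hypoxia replicate 1 camera passed 2 lists, leukocyte and miR-17-92, and without hypoxia replicate 2 it passed 2, leukocyte and miR-15/16. The leukocyte list had an adjusted p of 0.757 with an estimated correlation over all 6 libraries.

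**Figure D3:**
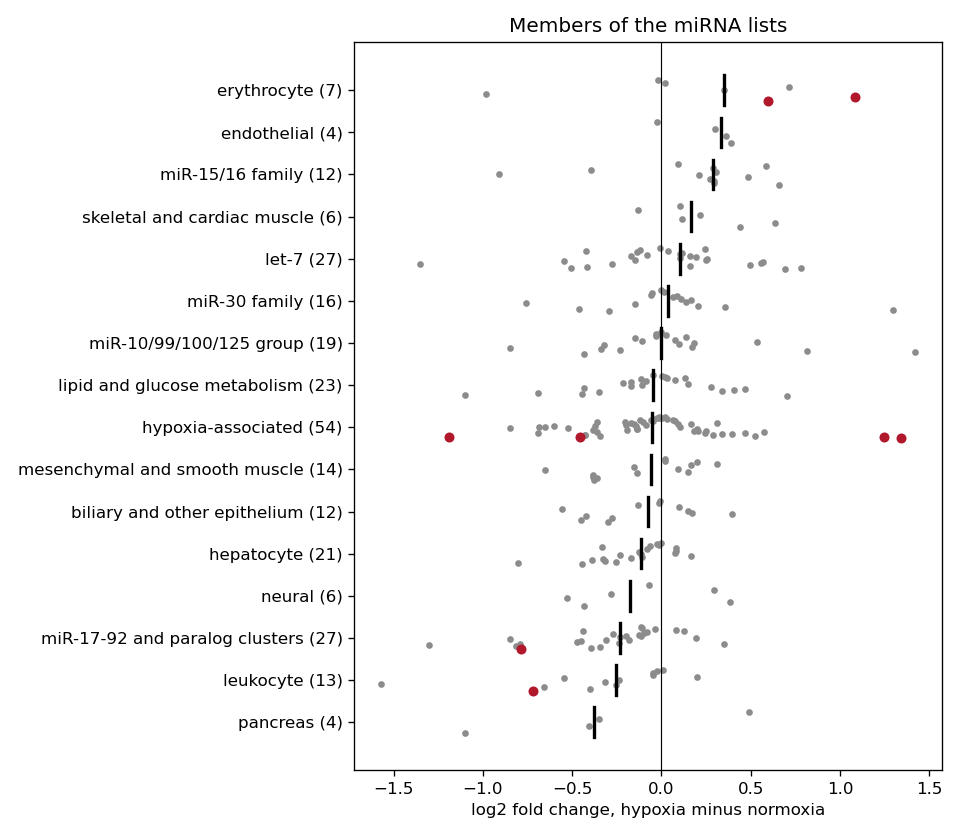
Each point is the log2 fold change, hypoxia minus normoxia, of a tested entry in 1 of the 16 lists, red where it passed the threshold and grey otherwise, and black bars are list medians. The numbers in brackets count tested entries, and 2 entries each of the hypoxia-associated and erythrocyte lists lie among the red points to the right of 0.

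Markers of cell types other than hepatocytes were measured in the same vesicles. In the leukocyte list 1 of 13 entries fell (the miR-146b-3p entry), and dre-miR-146a had a log2 fold change of -0.40 ± 0.10 (edgeR, Benjamini-Hochberg adjusted p = 0.076). Adjusted over the list alone, 2 fell. The list had a camera Benjamini-Hochberg adjusted p of 0.121. In the endothelial list 0 of 4 passed, with gmo-miR-126-3p_R-1 at 0.39 ± 0.10 and oni-miR-126 at -0.03 ± 0.20. Adjusted over the list alone, 1 rose, miR-126-3p. For skeletal and cardiac muscle 0 of 6 passed, with dre-miR-1 at 0.12 ± 0.16 and dre-miR-133a-3p_L-1R+1 at 0.44 ± 0.24. Nothing passed among 14 mesenchymal and smooth muscle entries, where dre-miR-199-5p led in abundance. The same held for 12 biliary and other epithelial entries, with dre-miR-200a-3p_R+1 at -0.30 ± 0.13 and dre-miR-200b-3p at -0.27 ± 0.14, and for 6 neural entries, with gmo-miR-128-3p at -0.07 ± 0.11 and dre-miR-124-3p_R-2_1ss20CT at 0.38 ± 0.19. The camera Benjamini-Hochberg adjusted p-values were 0.308 for endothelial, 0.295 for muscle, 0.692 for mesenchymal, 0.692 for epithelial and 0.730 for neural miRNAs. Of 4 pancreas entries 0 passed (0.502), with dre-miR-375_R-1 at -1.10 ± 0.38, dre-miR-216b at -0.41 ± 0.15, dre-miR-217_R+1 at -0.35 ± 0.16 and dre-miR-216a at 0.49 ± 0.24. The first 2 were the only ones of the list with an unadjusted p under 0.05, and dre-miR-375_R-1 stood at 219.3 CPM in normoxia replicate 1 against 48.2 to 102 CPM in the other 5 libraries.

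Of the large families, let-7 had 27 tested entries, the group of miR-10, miR-99, miR-100 and miR-125 had 19 and miR-30 had 16, and none of these entries passed. dre-let-7a lay at 0.11 ± 0.14, dre-miR-100-5p_R-1 at -0.03 ± 0.14, dre-miR-125b-5p at 0.03 ± 0.15, ssa-miR-30a-5p at -0.15 ± 0.10 and ssa-miR-30c-5p at 0.14 ± 0.11. Their camera Benjamini-Hochberg adjusted p-values were 0.692, 0.992 and 0.692. For let-7 the test and median pointed up while the mean log2 difference was -0.06, and for the miR-10 group the test pointed up with a median of -0.05, which lay at -0.14 to 0.05 with 1 library left out. Of the lists too small to test, the sensory cluster had 2 tested entries of 3, dre-miR-183-5p_R-1 and dre-miR-182-5p_R+2_1ss10GA, at -0.17 ± 0.36 and -0.71 ± 0.49. The p53-linked list had 1 tested entry of 3, dre-miR-34a, at 0.70 ± 0.22 (edgeR, Benjamini-Hochberg adjusted p = 0.112), and it did not pass. The fish maternal-clearance family miR-430 had 0 entries.

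Composition was close between groups. miR-122 took 23.23 ± 1.600% of counts in hypoxia and 24.3 ± 0.40% in normoxia (exact permutation p = 0.4), and the top 10 entries took 61.2 ± 0.49% and 62.0 ± 0.64% (exact permutation p = 0.2). Shannon diversity was 5.06 ± 0.05 bits in hypoxia and 5.02 ± 0.01 bits in normoxia, at the smallest two-sided exact permutation p the design allows (0.1). Total counts and entries detected each had an exact permutation p of 0.6, and the 5 Benjamini-Hochberg adjusted values lay at 0.5 to 0.6. Libraries differed in their trends on GC content and length. Deviations of log2 CPM from each entry's mean over the libraries were fitted jointly on both, for entries with a mean of at least 10 CPM. The slope per 10 points of GC was 0.110 and 0.112 in hypoxia replicates 1 and 3 and -0.063 in hypoxia replicate 2, against -0.010, -0.079 and -0.070 in normoxia replicates 1, 2 and 3. Slopes per nucleotide of length were -0.005, -0.066 and -0.030 in hypoxia replicates 1, 2 and 3, against 0.079, 0.043 and -0.021 in normoxia.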

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

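Each sequence taken at its listed value, every sequence kept apart, and the GC and length offsets were chosen after seeing the data. The 14 called entries kept their direction in each setting that fitted the same entries and tested them. In all 14 the groups did not overlap, so leaving out 1 library could hardly reverse a direction. Kept directions therefore add little to the calls. The direction of the 14 was not followed in the fits of sequences kept apart and of family and arm sums, which give other units. The count stayed within 1.5 times with DESeq2 size factors (14), upper quartile (13, of which 3 lower), a filter of 10 CPM (15), family and arm sums (16), known miRNAs only (10, of which 5 higher) and listed values (12). It was 5 with total counts only (5 higher, 0 lower), 59 with no filter (33 and 26), 51 with DESeq2 (27 and 24), 22 with limma-voom (15 higher), 3 with GC and length offsets (3 and 0), 6 with every sequence kept apart (5 and 1) and 8 with a 2-fold threshold (5 and 3). The last follows from its construction and for the others the cause was not tested. Leaving out 1 library gave 0 to 52 calls, 0 to 28 higher and 0 to 24 lower. The extremes were without normoxia replicate 2 (0) and without hypoxia replicate 2 (52). The median log2 fold change of all entries was -0.04, and -0.12 with no filter.

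With the replicate number as a block, 7 entries passed (4 higher, 3 lower), all 7 among the 14. Both miR-210 arms and miR-144-3p were among them. miR-451 and the miR-146b-3p entry did not pass (edgeR with the block, Benjamini-Hochberg adjusted p = 0.097 and 0.0996). Same-numbered libraries did not deviate together (correlations of -0.13, -0.06 and -0.05). Values from 3 libraries per group cannot exclude pairing, so whether the numbers pair the samples stays open. The block changed no list.

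The count of lists was 0 in the main analysis, 3 with fry and 0 to 2 with 1 library left out, and 0 with an estimated correlation, other scaling, no filter or listed values. The cause was not tested. The differences between groups in composition moved by less than 1 SD in every setting run, while the levels themselves can shift, as with entries detected at 10 counts (505 to 588 in normoxia, against 643 to 725 at 1 count). That SD includes the outlying hypoxia replicate 1, so the rule lets large moves pass. This library had 462 entries detected, below the normoxia range, while hypoxia replicates 2 and 3 lay within it at 681 and 657.

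Not every named entry was followed across settings. The 58 compared held the called, most abundant, miR-210 and miR-122 entries, the first members of each list and some others. Of these 58, 9 changed sign under at least 1 setting. Among them 0 were called, which follows in part from the groups of called entries not overlapping. Under total counts and upper quartile the median of all entries moved from -0.04 to 0.0081 and 0.017, so that values near 0 cross it by construction. oni-miR-126 lay at 0.021 with total counts, 0.029 with upper quartile, 0.018 with limma-voom and 0.061 with GC and length offsets. oni-miR-143_1ss20TA lay at -0.011 with the block, -0.010 with known miRNAs only and -0.00075 with the offsets. dre-miR-100-5p_R-1 lay at 0.021 with total counts and 0.031 with upper quartile, ssa-miR-30a-5p at 0.017 with the offsets, and dre-mir-451-p3 at -0.0075 with known miRNAs only. With 1 library left out, oni-miR-126 ranged from -0.14 to 0.22, oni-miR-143_1ss20TA ranged from -0.22 to 0.21, dre-miR-100-5p_R-1 ranged from -0.19 to 0.10, dre-miR-125b-5p ranged from -0.014 to 0.17, gmo-miR-128-3p ranged from -0.12 to 0.039, dre-miR-183-5p_R-1 ranged from -0.32 to 0.025, dre-miR-1 ranged from -0.034 to 0.28 and dre-mir-451-p3 ranged from -0.15 to 0.17. For the other settings the cause was not tested.

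The pseudocount and low-value filter alternatives apply to normalized values and were not run. At this depth a log2 change of 0.5 was recovered in 30.2% of simulated entries.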

Other observations

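Families below were chosen after their values were seen. Of 10 tested miR-26 entries, 9 had a lower fold in hypoxia and 2 of these fell. The abundant dre-miR-26b measured 10317 CPM in hypoxia and 13111 CPM in normoxia, a log2 fold change of -0.35 ± 0.10, and dre-miR-26a-5p_R+1_1ss21CT one of -0.43 ± 0.12, neither past the threshold. All 7 miR-19 entries had a lower fold, with a median log2 fold change of -0.11, and 0 had an unadjusted p under 0.05. Both arms of miR-2188, dre-miR-2188-5p and dre-miR-2188-3p_L+1_1ss14AG, had higher folds, at 0.47 ± 0.14 and 0.50 ± 0.19 (edgeR, Benjamini-Hochberg adjusted p = 0.106 and 0.193). dre-miR-462_R+1, of a cluster found in fish, had a log2 fold change of -0.31 ± 0.10 (0.125 by the same test). dre-miR-181a-2-3p had one of 0.52 ± 0.12 (0.066) and ccr-miR-457a_L+1R+1 one of 0.66 ± 0.16 (0.069). Normoxia replicate 1 stood apart in 2 miRNAs of endocrine pancreas, with dre-miR-375_R-1 at 219.3 CPM and ssa-miR-7a-5p at 136 CPM, where the other 5 libraries held 48.2 to 102 CPM and 12.8 to 50.5 CPM.

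Of the tests that follow, those of miR-210, of miR-451 with miR-144-3p and of CCA ends were chosen only after the result was seen. The 6 libraries in 2 groups allow 10 splits, too few for a share under 0.05. The real split called 14 entries and the highest other split 0, so that 1 of the 10 splits gave as many. For lists the real count was 0 and the highest other 3. A count of 0 is reached by 10 of the 10 splits by construction, so this says nothing of chance.

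Both miR-210 arms were higher in hypoxia. A trend of the libraries on GC content or length was argued against as the whole cause, because with offsets for it the lower of the 2 log2 fold changes was 0.97 and both passed. The shallow hypoxia replicate 1 was argued against as the whole cause by effect size only, since without it the lower log2 fold change was 1.19. Without that library the 5p arm passed and the 3p arm did not (edgeR, Benjamini-Hochberg adjusted p = 0.015 and 0.053). A response to hypoxia, the difference the design names, was not tested apart from the grouping itself and stays open, as does chance with 10 splits.

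miR-451 and miR-144-3p were higher in hypoxia. More erythrocyte RNA of an unaltered profile would raise both strands of miR-451 alike, but the ratio of miR-451 to its opposite strand was 16.7 to 19.8 in hypoxia and 11.4 to 13.2 in normoxia, a difference of 0.60 ± 0.10 (SE) in log2 ratio (exact permutation p = 0.1, the smallest possible). The corresponding difference for miR-144-3p was 0.73 ± 0.22 (exact permutation p = 0.1). The entry taken as its opposite strand, oni-miR-144a_L-1R+1_1ss11TA, itself had a log2 fold change of 0.35 ± 0.20. Both miRNAs were picked because they were called, while their opposite strands were not, so these differences partly restate the calls. The ratios therefore cannot settle whether the hypoxia preparations held more erythrocyte RNA. A trend on GC content or length was argued against as the whole cause by effect size, with log2 fold changes of 0.76 and 1.22 after offsets. With these offsets miR-451 passed and miR-144-3p did not (edgeR, Benjamini-Hochberg adjusted p = 0.015 and 0.071). More erythrocyte RNA stays open. Altered miRNA content of erythrocytes or another source stays open too and was not tested.

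The 29 tested entries of 18 nt with names of known miRNAs had a median log2 fold change of 0.56, with 25 higher, against -0.02 for entries of 22 nt. The 18-nt entries lay 0.44 (95% bootstrap interval 0.13 to 0.69) above the GC trend of entries of 21 to 24 nt. That interval leaves out the error of the trend, which was fitted once. Median GC was 61.1% at 18 nt and 40.9% at 22 nt, so the trend was carried to higher GC. Entries in the trend had a floor of 10 CPM and the 18-nt entries none. The test therefore cannot exclude GC content alone. A shift of read length over whole libraries may contribute. Among length variants of 30 miRNA arms, the log2 fold change had a slope of -0.069 per nucleotide (95% interval -0.12 to -0.01). Only variants of at least 20 nt and a mean of at least 10 CPM entered this slope. It was shallower than the -0.14 between the medians at 18 and 22 nt, which covers other lengths and has no CPM floor. Fragments of tRNA 3′ ends may contribute too: among entries of 18 to 20 nt, 15 ending in CCA, the end of mature tRNA, lay 0.41 above 62 others (permutation p = 0.018). Length was not held fixed in this permutation, and the CCA-ending median of 0.59 lay near the 0.56 of the 18-nt entries. The test therefore cannot separate CCA ends from length. CCA-ending entries took 0.0329 to 0.0363% of counts in the 3 hypoxia libraries and 0.0162 to 0.0258% in the 3 normoxia libraries. All known-miRNA entries of 18 to 20 nt took 5.23 to 6.17% in hypoxia and 4.90 to 5.27% in normoxia, where the groups overlapped. Entries are not independent replicates, and GC content, read length and tRNA fragments all stay open.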
